A study of Rattus norvegicus with 48 samples.

How the data were processed

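RNA sequencing libraries from precision-cut rat liver slices were analysed, 48 in 5 groups as the labels give them. Total RNA was prepared with the RNeasy 96 kit and libraries with standard Illumina protocols, per the labels' protocols. RSEM, which estimates counts per gene from reads, and edgeR are named with no versions, and the genome build is Rnor_6.0, per the submitters' processing notes. The aligner, annotation release and filters are not given in the sources used here.

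The deposited count table holds expected counts for 32883 genes, not normalised, of which 8.02% were not whole at a tolerance of 1e-06; they were rounded to whole numbers before any count test. A 2nd table, deposited by the authors, holds log2 CPM values for 14418 genes that its name describes as expressed and protein coding; 13820 of them were among the genes tested here. A table of 172 quality metrics per library was also deposited by the authors; it mixes percent values, counts and other scores, and 151 of the metrics varied between libraries and entered a principal component analysis whose first component held 35.7% of their variance. A sample sheet gave the same group names as the labels for all libraries except the 9 of BDL_SB525334. No column of per-library values was left unused. The labels give no strand setting, so overlapping and antisense genes cannot be told apart, and counts of near-identical genes are uncertain.

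Genes were filtered with edgeR's filterByExpr by group, which left 14775, and libraries were scaled with TMM factors. The quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest; R 4.3.3) was fitted to all 48 libraries at once, with 1 coefficient per group and no covariate, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. There were 7 comparisons. All tests were two-sided. Standard errors of log2 fold changes were derived from the F statistic. Log2 CPM for principal components and axis scores used a prior count of 2. Library measures were compared with permutation tests of the difference in means in SciPy 1.17.1 (Python 3.11.15), exact where a group held fewer than 10 libraries and with 100000 draws otherwise, and adjusted over 126 tests. The ligation axis used the 11569 genes called between sham libraries and the 5 odd-numbered vehicle libraries; the 5 even-numbered ones were held out and scored like the compound libraries.

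Total counts ranged from 12249470 to 29596987 per library, so that 3 counts, taken as the upper limit that a count of 0 allows, correspond to 0.101 to 0.245 CPM. A fold against a group at 0 was computed against 3 counts over the group. Intervals at the 95% level and floors cover counting error only, since no molecular identifiers were used here. No 2 libraries of a group matched within sampling noise: over 207 pairs the lowest chi-square per degree of freedom was 3.94, over genes with at least 20 counts. The test was tested on simulated data for each comparison, with 50 changed genes per fold size. Changed genes were drawn from those with a mean of at least 1 CPM in ligated vehicle libraries, so recovery of scarcer genes was not tested. Only the drawn genes changed, evenly up and down, from 1 level per gene shared by all groups. The simulations therefore cannot show errors that come from the scaling of libraries. In the real data 82.21% of genes were called for ligation, 72.99% for SB525334 and 24.28% for Nint against vehicle, so recovery and false calls can differ there. For ligated against sham slices it recovered 48% of genes changed by 1.25-fold, 74% at 1.5-fold, 90% at 2-fold and 96% at 4-fold among 14451 genes, with 0 in the wrong direction and 13 false calls. For SB525334 against vehicle these were 42%, 62%, 94% and 100% among 14456 genes, with 11 false calls, and for Sora 42%, 70%, 84% and 100% among 14458 genes, with 9. For Nint against vehicle these were 34%, 72%, 96% and 96% among 14446 genes, with 8. Shared vehicle libraries were treated by 20 simulations of unchanged groups and by splitting the vehicle libraries into odd and even numbers.

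Groups, comparisons, tests, most alternatives and the rules for naming genes were fixed before the data were examined. The alternatives were RLE factors, DESeq2 1.42.0, no filter, a filter of 5 CPM in at least 9 libraries, fits of the 2 groups alone, limma-voom with sample weights (limma 3.58.1), limma on the authors' log CPM, replicate number as a block, plate column, the quality component, 3 surrogate variables (sva 3.50.0) and a log2 fold threshold of 1. Total counts, leaving out the 50 most abundant genes, leaving out vehicle libraries 3 and 6 and leaving out each library in turn were chosen after seeing the data. The IDs are Ensembl IDs, and the reference table used here (assembly GRCr8, 47357 genes) holds 0 Ensembl IDs, so 0 of 32883 IDs had a symbol. The 26 gene lists fixed in advance, a fibrosis panel, the compound targets and the rule for named genes all need symbols and could not be run. In their place 4 IDs were taken by a rule adapted after the values were seen: the largest called rise and fall for ligation, and the largest over the 3 compounds against vehicle, among genes with a mean of at least 5 CPM in either group compared. Both of the latter fell on SB525334.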

Results

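RNA was sequenced from precision-cut slices of rat liver, thin sections of living tissue studied outside the body, in a slice model for evaluating compounds against fibrosis. The slices came from sham-operated rats or from rats with bile duct ligation (BDL), an operation that blocks bile flow and leads to cholestatic fibrosis. The 48 libraries fell into 5 groups: sham slices with vehicle (Sham_veh, n = 9), ligated slices with vehicle (BDL_veh, n = 10), and ligated slices with Sora (BDL_Sora, n = 10), Nint (BDL_Nint, n = 10) or SB525334 (BDL_SB525334, n = 9). Sora and Nint are read here as sorafenib and nintedanib, 2 multikinase inhibitors; the labels give only the short forms. SB525334 is an inhibitor of the TGF-beta type I receptor kinase ALK5. The deposited sample sheet names that group by another compound code in 9 of 9 libraries, so its identity rests on the labels. Total counts per library ranged from 12249470 to 29596987, with group medians of 16766306 (Sham_veh), 14392510 (BDL_veh), 14632850 (BDL_Sora), 13629248 (BDL_Nint) and 14107981 (BDL_SB525334). The labels give no doses, exposure times or animal numbers, so the p-values measure only the spread between these libraries, which may be technical. The files name genes by Ensembl ID and do not pair the IDs with symbols, so gene groups are described by their own behaviour across the groups. Of single genes, 2 IDs that rose and 2 that fell are given, and they were chosen by size of change after the values were seen.

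Libraries separated first by ligation and then by SB525334. The first principal component held 57.2% of the variance and put the sham libraries at 154.1 ± 7.98 (SD, n = 9) and the ligated vehicle libraries at -48.4 ± 6.62 (n = 10). The second held 16.4% and set the SB525334 libraries, at 80.1 ± 26.3 (n = 9), apart from the other 4 groups, whose means lay between -21.2 and -11.8. Within the SB525334 group this score ranged from 37.1 to 108, and unevenly. Libraries 1, 6 and 8 scored 51.2, 53.7 and 37.1, and the others 80.55 or more. The same libraries had the lowest shares of non-uniquely mapped reads of the group (11.27%, 9.85% and 10.94%, the others 13.42% or more). Means of this group therefore cover an uneven set of libraries. The third component, with 6.7%, set BDL_veh, at 34.8 ± 16.4, above every other group, sham included. BDL_Sora lay at -14.8 ± 21.6, BDL_Nint at -14.1 ± 15.6, BDL_SB525334 at -8.91 ± 23.2 and Sham_veh at 2.29 ± 14.5. This component therefore does not show a compound effect by itself. Vehicle libraries 3 and 6, at -4.91 and 15.95 on it, lay nearer to the compound groups and to sham than the other 8 vehicle libraries did.

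**Figure D1:**
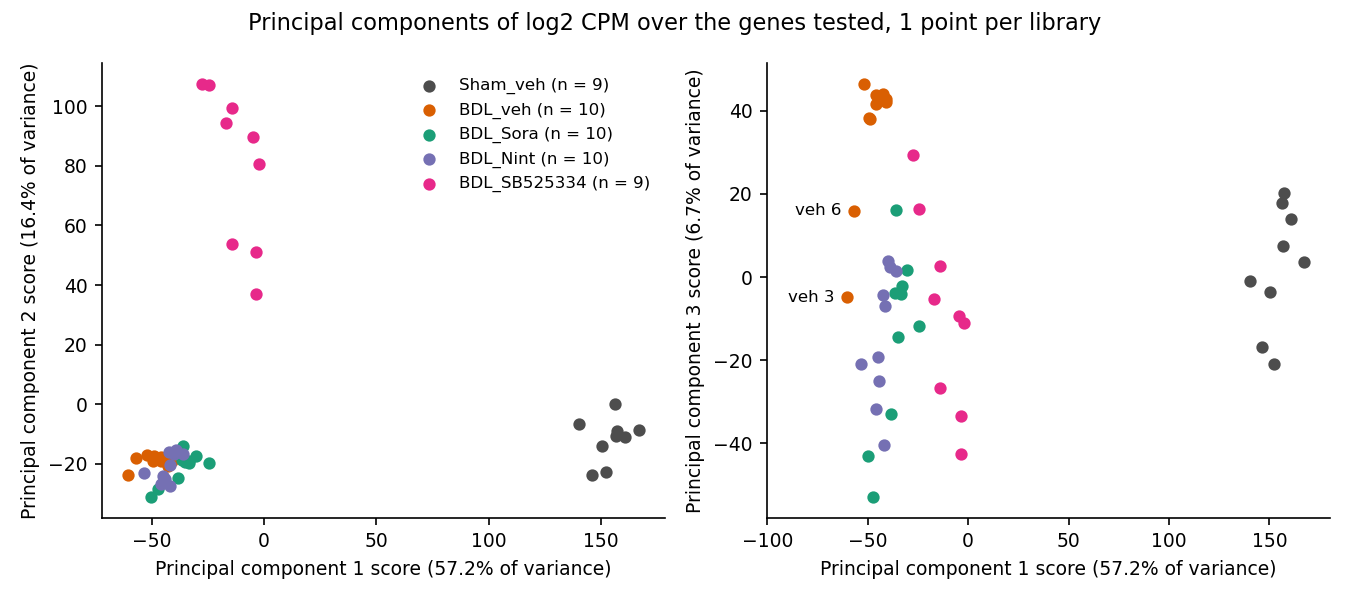
Scores of the 48 libraries on principal components of log2 CPM, with component 1 on both horizontal axes and components 2 and 3 on the vertical axes; each point is a library, coloured by group. Sham libraries sit near 154.1 on component 1, SB525334 libraries between 37.1 and 108 on component 2, and vehicle libraries 3 and 6 (marked veh) below the other vehicle libraries on component 3.

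The effect of ligation was read from ligated against sham slices, both with vehicle. Of 14775 genes tested, 5911 were higher and 6235 lower in ligated slices (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05; n = 10 and 9). The large changes were mostly increases: 3798 genes rose and 1897 fell by 2-fold or more, and 961 rose and 67 fell by 16-fold or more. Scarce transcripts mostly rose and abundant ones mostly fell. Of 4117 genes with a mean of 1 to 10 CPM, 52.3% rose and 26.9% fell, while of the 80 genes at 1000 CPM or more 18.8% rose and 67.5% fell. Both patterns kept their direction with TMM factors, RLE factors, DESeq2 size factors and total counts, the last with 62.1% and 17.6% for the scarce and 26.2% and 53.8% for the abundant genes. Genes at 10 to 100 CPM turned, from 34.6% rising and 49.2% falling to 50.5% and 30.5% with total counts. Genes switched on by ligation, at 1 CPM or more in every ligated vehicle library and under 1 CPM in every sham library, numbered 678, and 67 showed the opposite switch. With total counts in place of TMM factors these were 807 and 49. Unchanged values separate 9 from 10 libraries completely, in either direction, in a share of 2.17e-05 of arrangements.

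ENSRNOG00000029949 had 0 counts in 9 sham libraries and 16.4 ± 13.1 CPM in ligated vehicle slices (SD, n = 10). Pooled over libraries, this is at least 719-fold higher than a floor of 3 counts over the sham group, and at least 584-fold higher at the lower limit of the 95% counting interval (edgeR adjusted p = 4.26e-08). ENSRNOG00000048576 fell from 8.13 ± 5.54 CPM (n = 9) to 1 count over 10 ligated libraries, a ratio of 1420 with a 95% counting interval of 254 to 56000 (edgeR adjusted p = 2.63e-22). ENSRNOG00000003263 rose from 0.163 ± 0.132 CPM in sham slices to 32.3 ± 8.38 CPM in ligated ones, a log2 fold change of 7.53 (SE 0.453, edgeR adjusted p = 4.24e-20). Fitted log2 changes of the first 2 genes, which depend on the prior count, were 10.97 and -9.17, with ranges over the alternatives of 8.61 (limma-voom) to 11.13 and -9.17 to -4.86 (quality covariate), the latter a smaller change than the counting interval of 254 to 56000 covers. For the third gene the range was 7.48 to 8.12. Directions of change are relative to the scaling of the libraries. The median log2 difference of all genes was -0.030 with TMM factors and 0.31 with total counts, which gave 7861 increases and 4035 decreases (4525 and 1040 of 2-fold or more), 66.1% increases against 48.7%. Increases were also in the majority, at 52.9%, with RLE factors and with DESeq2.

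**Figure D2:**
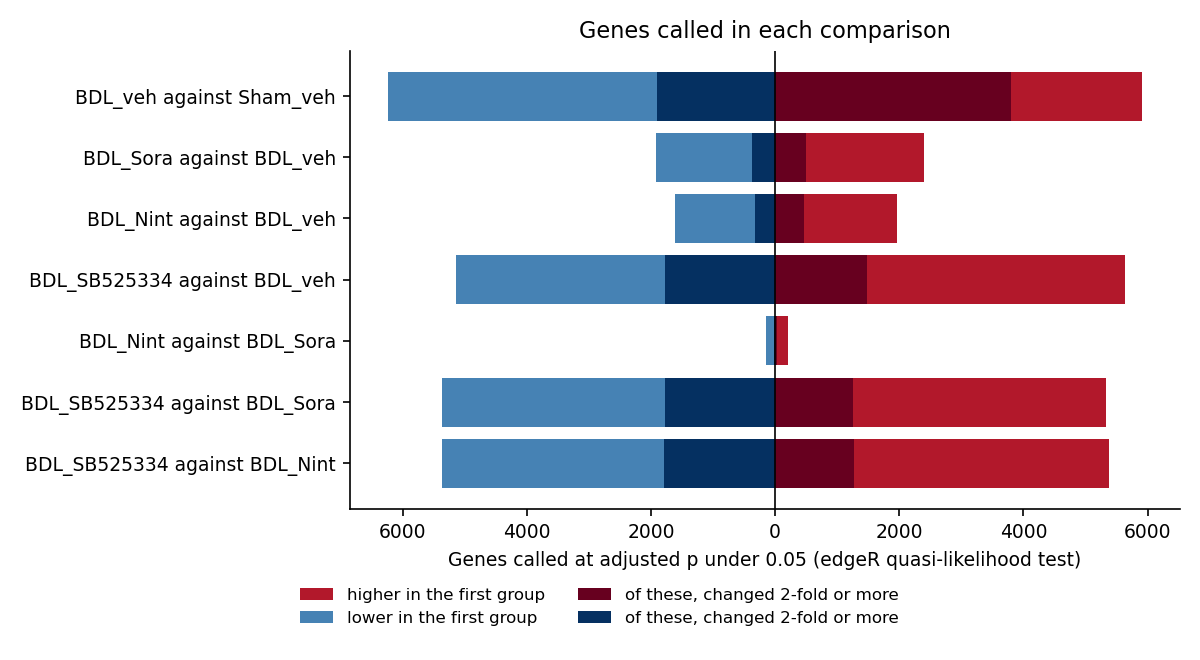
Number of genes called in each of the 7 comparisons, to the right of 0 where the first group was higher and to the left where it was lower; darker parts are changes of 2-fold or more. Ligation and SB525334 changed 12146 and 10785 genes, BDL_Sora and BDL_Nint 4323 and 3587.

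Ligation also changed the RNA classes and the shape of the libraries, as recorded in the authors' quality metrics and the counts. The mitochondrial share of mapped alignments was 2.25 ± 0.142% in sham and 1.42 ± 0.0644% in ligated vehicle slices, and the lincRNA share 1.12 ± 0.101% and 0.62 ± 0.049%. The intronic share rose from 27.4 ± 2.13% to 35.6 ± 0.895%. The number of genes at 1 CPM or more rose from 12171 ± 89.0 to 13647 ± 105. The 100 most abundant genes took 34.6 ± 1.66% of counts in sham slices and 27.8 ± 1.01% in ligated ones. For each of these 5 measures the 9 sham and 10 ligated libraries did not overlap (two-sided exact permutation test, adjusted p = 6.51e-05 over 126 tests, from p = 2.17e-05, the smallest these libraries can give).

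SB525334 moved these measures as well. Its slices had a mitochondrial share of 2.86 ± 0.677% (n = 9), an intronic share of 29.97 ± 2.07%, 12986 ± 207 genes at 1 CPM or more and 35.8 ± 2.20% of counts in the 100 most abundant genes, with no overlap with ligated vehicle libraries (exact permutation test, adjusted p = 6.51e-05 for each). Non-uniquely mapped reads were 14.4 ± 3.44% of reads with SB525334 and 8.54 ± 0.235% with vehicle, and misc_RNA 2.73 ± 0.582% and 1.66 ± 0.107% of mapped alignments (exact permutation test, adjusted p = 6.51e-05 for each). BDL_Sora had a mitochondrial share of 1.72 ± 0.105%, above vehicle (permutation test, adjusted p = 0.000202), an intronic share of 32.9 ± 1.14% (adjusted p = 0.000233) and a lincRNA share of 0.513 ± 0.025%, below vehicle (adjusted p = 0.000202). BDL_Nint lay closer to vehicle, with 1.51 ± 0.0959% mitochondrial (permutation test, adjusted p = 0.0486) and 35.2 ± 0.817% intronic alignments (adjusted p = 0.365).

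**Figure D3:**
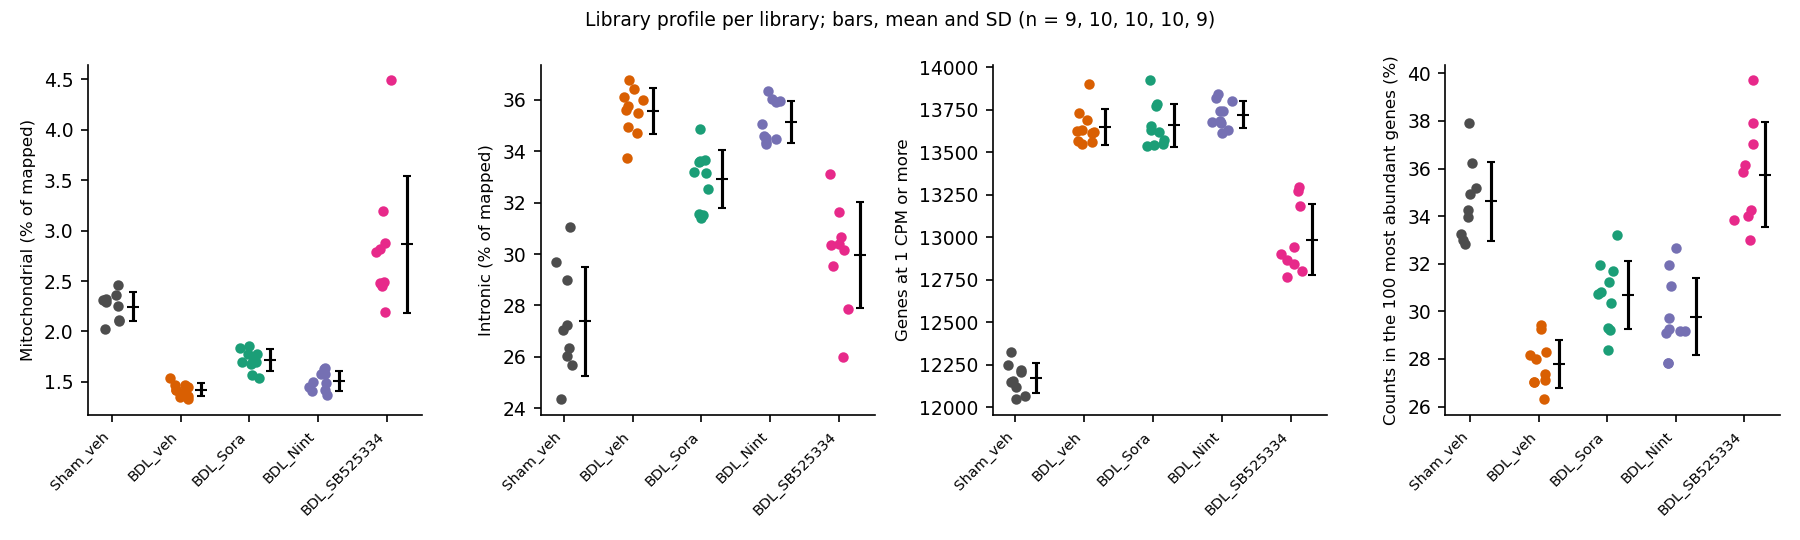
Mitochondrial and intronic shares of mapped alignments, genes at 1 CPM or more, and the share of counts in the 100 most abundant genes; each point is a library and bars give the mean and SD per group. The SB525334 libraries, with means of 2.86%, 29.97%, 12986 and 35.8%, lie apart from the ligated vehicle libraries in each panel.

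Slices with Sora were compared with vehicle slices, both from ligated rats. Sora raised 2406 genes and lowered 1917 (edgeR adjusted p under 0.05; n = 10 and 10), of which 492 rose and 372 fell by 2-fold or more. Genes that ligation had raised mostly fell where they changed: of 5911, 1483 fell and 666 rose. Of the 961 genes that ligation had raised 16-fold or more, 40.4% fell and 9.68% rose, and of the 2113 raised by under 2-fold 17.0% fell and 10.5% rose. Of 6235 genes lowered by ligation, 1401 rose and 224 fell. These directions were the same with each of the 4 scalings, but less uneven for the lowered genes with the other 3: 1077 rose and 356 fell with RLE factors, 1156 and 384 with DESeq2 and 872 and 458 with total counts. Of the 2113 genes, 24.5% fell and 6.63% rose with total counts. Among genes that ligation had lowered by under 2-fold, the direction turned with total counts, and more fell than rose. ENSRNOG00000003263 fell by 2.98 on the log2 scale (SE 0.293, edgeR adjusted p = 5.46e-11), to 4.09 ± 2.78 CPM. ENSRNOG00000006368 was at 0.305 ± 0.234 CPM against 0.107 ± 0.0998 in vehicle slices (log2 fold change 1.43, edgeR adjusted p = 0.041). That call was lost without a filter on low counts, with plate column as a factor and with a quality covariate (adjusted p = 0.0551, 0.0942 and 0.101), and the range over 12 alternatives was 0.0204 to 0.101. Increases made up 55.7% of calls with TMM factors, 44.8% with RLE factors, 45% with DESeq2 and 38.1% with total counts (1598 increases, 2596 decreases), and limma-voom with sample weights called 7581 genes.

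Slices with Nint gave a similar count. Nint raised 1971 genes and lowered 1616 (edgeR adjusted p under 0.05; n = 10 and 10), with 468 and 331 changed by 2-fold or more. The balance of all calls depended on the scaling, with 1725 increases and 1922 decreases with RLE factors, 1872 and 2067 with DESeq2 and 1626 and 1914 with total counts. Of the genes ligation had raised, 1209 fell and 729 rose, and of those it had lowered, 993 rose and 241 fell, again with the same direction under the 4 scalings. For the lowered genes these were 855 and 367 with RLE factors, 918 and 404 with DESeq2 and 794 and 371 with total counts. Among the 961 strongest ligation increases 33.4% fell and 14.9% rose with Nint. Among the 374 genes that ligation had lowered by 4 to 16-fold, 44.1% rose with Nint and 55.1% with Sora. ENSRNOG00000003263 fell by 2.11 on the log2 scale (SE 0.28, edgeR adjusted p = 8.22e-08), to 7.46 ± 3.55 CPM. Limma-voom with sample weights called 6452 genes, and a fit of the 2 groups alone 5674.

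SB525334 was called against vehicle in more genes than Sora or Nint, and direct comparisons with both follow. It raised 5642 and lowered 5143 against vehicle (edgeR adjusted p under 0.05; n = 9 and 10), of which 1481 rose and 1768 fell by 2-fold or more. Large changes were mostly decreases: 71 genes fell and 22 rose by 16-fold or more. Of the 5911 genes raised by ligation, 2889 fell and 1482 rose, and among the 961 raised 16-fold or more 66.6% fell and 13.5% rose, a median log2 fold change of -1.08. Both directions held with each of the 4 scalings, and with total counts 4011 fell and 737 rose, and 77.4% and 7.7% of the 961. Of the 6235 genes lowered by ligation, 3297 rose and 1360 fell, but with total counts 1612 rose and 3013 fell, since the median log2 difference of all genes was then -0.39 against 0.014 with TMM factors. Genes at 1000 CPM or more rose in 62.5% of cases and fell in 8.75%, and genes at 1 to 10 CPM fell in 43.5% and rose in 25.0%, the opposite of the ligation pattern and in the same direction under the 4 scalings. With total counts these were 45% and 27.5%, and 60.4% and 14%, and the 7659 genes at 10 to 100 CPM turned, from 42.8% rising and 33.5% falling to 19.2% and 60%, as did those at 100 to 1000 CPM, from 59.3% and 20.9% to 31% and 49.2%.

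With SB525334, ENSRNOG00000003263 fell to 0.136 ± 0.143 CPM, beside 0.163 ± 0.132 CPM in sham slices (log2 fold change -7.86, SE 0.479, edgeR adjusted p = 3e-19). ENSRNOG00000006368 rose from 0.107 ± 0.0998 to 8.46 ± 5.20 CPM (log2 fold change 6.25, SE 0.45, edgeR adjusted p = 5.31e-17), while sham slices held 0.104 ± 0.122 CPM. This gene stood at 2.10, 3.58 and 2.73 CPM in SB525334 libraries 1, 6 and 8 and at 6.64 or more in the others. Its log2 fold change was 4.52 with the quality covariate, and that of ENSRNOG00000003263 was -8.56 from the authors' log CPM. ENSRNOG00000029949 fell to 0.892 ± 1.85 CPM (log2 fold change -4.12, SE 0.814, edgeR adjusted p = 2.68e-05). SB525334 libraries 1 and 6 held 5.09 and 2.94 CPM and the others 0, so this mean describes no typical library. Vehicle libraries ranged from 3.10 to 44.8 CPM, and Sora library 6 and Nint library 5 also held 0. The call for SB525334 was lost with the quality covariate and with limma-voom (adjusted p = 0.065 and 0.0899). The range over 14 alternatives was 1.77e-08 to 0.0899, with log2 fold changes of -7.83 (authors' log CPM) to -2.99 (quality covariate). In the same gene Sora and Nint gave 6.33 ± 5.20 and 6.13 ± 4.62 CPM (edgeR adjusted p = 0.103 and 0.108 against vehicle, with ranges of 0.0091 to 0.334 and 0.0357 to 0.452 over 14 alternatives). SB525334 lay below Sora by a log2 fold change of -2.74 and below Nint by -2.70 in this gene (edgeR adjusted p = 0.0029 and 0.00333). Increases were 52.3% of calls with TMM factors, 47.5% with RLE factors and with DESeq2, and 24.5% with total counts (2767 increases, 8516 decreases; 684 and 3228 of 2-fold or more).

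**Figure D4:**
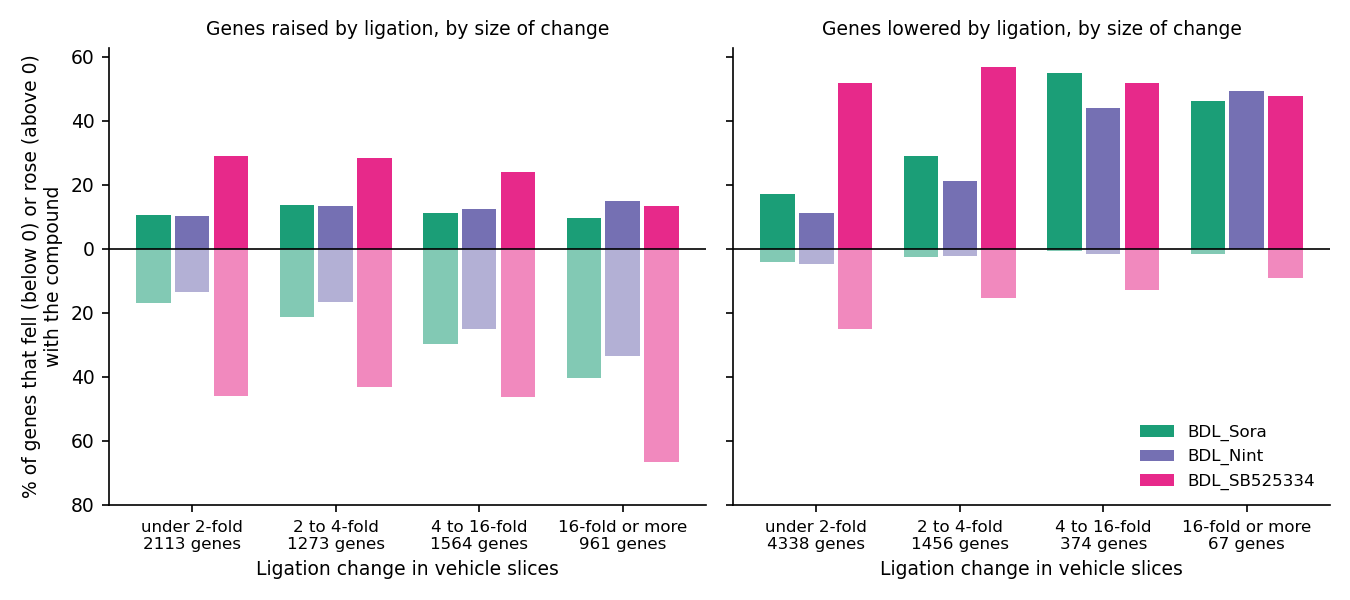
Percent of genes raised (left) or lowered (right) by ligation, by size of the ligation change, that rose (above 0) or fell (below 0, paler) with each compound in ligated slices. Of the 961 genes raised 16-fold or more, 66.6% fell with SB525334, 40.4% with Sora and 33.4% with Nint; with total counts more genes fell than rose with SB525334 among those lowered by under 4-fold, and with Sora among those lowered by under 2-fold.

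The compounds were then compared directly. Nint and Sora differed in 343 genes, 203 higher and 140 lower with Nint (edgeR adjusted p under 0.05; n = 10 and 10), and 40 of these differed by 2-fold or more. SB525334 differed from Sora in 10691 genes and from Nint in 10746, with 3028 and 3057 at 2-fold or more. ENSRNOG00000003263 was lower with SB525334 than with Sora by a log2 fold change of -4.87 and than with Nint by -5.74 (edgeR adjusted p = 2.19e-11 and 5.21e-14). Between Nint and Sora it differed by 0.87 (SE 0.288, edgeR adjusted p = 0.0978). The lincRNA share was higher with Nint than with Sora, 0.605 ± 0.0357% and 0.513 ± 0.025%, with no overlap between the 10 and 10 libraries (permutation test, adjusted p = 0.000168). The count of 343 was 598 with DESeq2, 1605 from the 2 groups alone, 3695 with limma-voom, 161 with plate column as a factor and 171 from the authors' log CPM. It was 567 without Sora library 3, 191, 166 and 228 without Sora libraries 5, 6 and 8, and 212 and 195 without Nint libraries 1 and 7. The count of 40 at 2-fold or more was 139 with limma-voom, 24 from the authors' log CPM, 22 with the filter of 5 CPM, and 62 without Sora library 3. With total counts 78.4% of the Nint and Sora differences were increases, against 59.2%, and for SB525334 increases were 25.5% against 49.8% (Sora) and 23.9% against 50.1% (Nint).

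Sora and Nint changed largely overlapping genes. Both raised 1457 genes and both lowered 1254, and 2 genes were called in opposite directions. Independent lists of these sizes would share 321 increases and 209.7 decreases. Simulated unchanged groups against the same vehicle libraries called at most 1 gene per comparison, so they give no chance value for shared calls. The covariance of their log2 fold changes across genes was 0.231, against 0.0166 in simulated unchanged groups. With the vehicle libraries split between the 2 contrasts the correlation across genes was 0.786 and 0.788, and genes are not independent replicates. Sora and SB525334 shared 1276 increases and 1185 decreases (independent lists 918.8 and 667.3) with 760 genes in opposite directions, a covariance of 0.213 and split correlations of 0.419 and 0.328. For Nint and SB525334 these were 1067, 1012 and 640 genes (independent lists 752.6 and 562.5), 0.189, and 0.387 and 0.297. The simulated covariances were 0.0169 and 0.0166. The 760 and 640 genes in opposite directions were 427 and 385 with the quality covariate, 1430 and 1331 from the 2 groups alone, 1819 and 1599 with limma-voom, and with vehicle libraries split 326 and 479 (Sora) and 275 and 368 (Nint). For Sora and Nint, the 2 groups alone gave 30 such genes and limma-voom 70.

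Against the ligation change, each compound moved more genes back than further away. Of 12146 genes changed by ligation, Sora moved 2884 in the opposite direction and 890 in the same, Nint 2202 and 970, and SB525334 6186 and 2842. From the 2 groups alone the opposite and same counts were 3742 and 1356 (Sora) and 3063 and 1726 (Nint). With limma-voom they were 4872 and 1712 (Sora) and 3434 and 2166 (Nint). For SB525334 with the quality covariate they were 4291 and 1214. With vehicle libraries split the counts in the same direction were 598 and 445 (Sora) and 621 and 511 (Nint). Independent lists would give 1782 and 1772, 1478 and 1470, and 4438 and 4428 genes. The vehicle libraries are shared by both contrasts, and simulated unchanged groups gave a covariance of -0.0165 across genes, against -0.348 (Sora), -0.245 (Nint) and -0.763 (SB525334). Correlations in these simulations were -0.477, -0.48 and -0.459, and in the data without a split -0.359, -0.262 and -0.409. Shared vehicle libraries alone can thus give correlations of this size when they are not split. With vehicle libraries split, correlations across genes were -0.313 and -0.363 for Sora, -0.225 and -0.265 for Nint, and -0.402 and -0.395 for SB525334. Slopes on the ligation change over all genes tested were -0.0974 and -0.0985 for Sora, -0.0677 and -0.0691 for Nint, and -0.221 and -0.213 for SB525334 in these splits.

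Each library was also placed on an axis over 11569 genes from ligated vehicle slices (0) to sham slices (100), with 5 vehicle libraries held out. Held-out vehicle libraries scored -0.398 ± 2.71 (n = 5), Nint 6.72 ± 2.07 (n = 10), Sora 9.73 ± 3.15 (n = 10) and SB525334 22.4 ± 4.87 (n = 9). Differences from held-out vehicle were 7.12, 10.1 and 22.8 (two-sided exact permutation tests, adjusted p = 0.0016, 0.00133 and 0.0015 over 6 tests). For Sora and SB525334 the unadjusted p of 0.000666 and 0.000999 were the smallest these libraries can give. All 10 Sora and 9 SB525334 libraries, and 9 of 10 Nint libraries, lay above every held-out vehicle library. SB525334 exceeded Sora by 12.7 and Nint by 15.7 (exact permutation tests, adjusted p = 0.00013 for each), and Nint lay below Sora by -3.01 (permutation test, adjusted p = 0.019). None of the settings used for this axis adjusted for library quality. Mean mitochondrial, lincRNA and intronic shares with SB525334 also lay nearer to sham than those of vehicle slices. The same held for genes at 1 CPM or more and the share of the 100 most abundant genes. Other measures, such as the snoRNA and scaRNA shares, went the other way. How much of the SB525334 score goes with library quality cannot be told here.

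**Figure D5:**
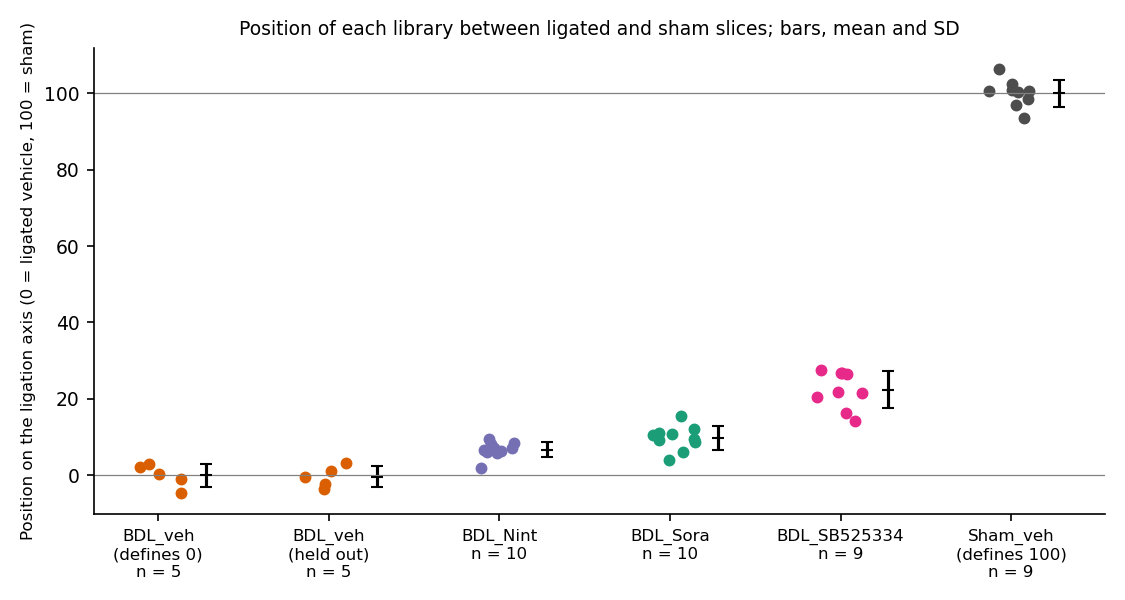
Position of each library between ligated vehicle slices (0) and sham slices (100) on the vertical axis, by group; points are libraries and bars give the mean and SD. Held-out vehicle libraries centre on -0.398, Nint on 6.72, Sora on 9.73 and SB525334 on 22.4.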

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

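The comparison of the compound code with the labels, the tests of vehicle library 3 alone and library 6 alone, the fit without the 50 most abundant genes and the fits with single libraries left out were chosen only after the results were seen.

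Over 19 measures 93 groups were searched for a library whose gap to the nearest other library was large against the range of its group, which chance gives in about 1 in 20 groups, and 11 values stood apart. Sora library 6 held 29596987 counts, with the next at 19953512. Nint library 3 held 20392041, with the next at 16262422. SB525334 library 4 had 4.49% mitochondrial alignments, with the next at 3.19%, and 8.311% of counts in its most abundant gene, with the next at 4.936%. Nint library 9 had 0.05% scaRNA against 0.04% in the others, and 3.462% of counts in its most abundant gene against 2.376% in the next. Nint library 5 had 8.76% non-uniquely mapped reads, with the next at 8.38%. Vehicle library 3 had 13900 genes at 1 CPM or more, with the next at 13728. Nint library 7 scored 1.832 on the ligation axis, with the next at 5.904. ENSRNOG00000048576 had 0.0694 CPM in vehicle library 9 and 0.0633 CPM in Sora library 5, 1 count each, with 0 in the other libraries of both groups.

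SB525334 was called in 10785 genes against vehicle, beside 4323 for Sora. Without the 50 most abundant genes 10729 genes were called, and 98.2% of the reported calls were kept. TMM factors already limit the weight of extreme genes in both fits. This fit could therefore hardly have differed, and it cannot tell whether a few dominant genes matter. With total counts, which do not limit that weight, 11283 genes were called, 24.5% of them increases. With the quality component as a covariate 7437 genes were called, a ratio of 1.45, which ranged from 1.39 to 1.54 as each of 19 libraries was left out and was 1.54 without SB525334 library 6, so it is not clear of the bound of 1.5 set in advance. That component mixes metrics and was also highest in the vehicle libraries with the most counts, so it does not stand for RNA quality alone. What it records, RNA quality included, may account for part of the calls. This cannot be told apart from the treatment, which moves the same metrics. The sample sheet gives the label's name for 0 of 9 libraries, and a code can be another name of the same compound, so the identity of the compound stays open beside a biological effect.

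Vehicle libraries 3 and 6 leaned toward the compound groups on axes from vehicle (0) to Sora or Nint (100), with 48.03 and 50.88 for library 3 and 18.93 and 18.51 for library 6, beside -15.4 to 5.68 and -12.0 to 1.75 for the other 8 vehicle libraries. Library 6 lay below the lowest held-out compound libraries (57.8 for Sora, SD 18.6; 71.6 for Nint, SD 17.1) by more than 1 SD, while library 3 lay within 1 SD of the lowest Sora library. On the ligation axis, however, libraries 3 and 6, held out, scored -2.61 and -3.57, below the lowest library of each compound group by at least 2.99 and 2.44 SD, which argues against the label of a compound group for either; a sample from outside these groups was not tested. On the quality component 1 of the pair lay outside the range of the other 8 (0.5495 to 1.716), library 6 at 0.465, and library 3 lay inside at 0.941, so RNA quality stays open for library 6. No biological explanation was tested, since both carry the vehicle label.

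The Sora and Nint changes correlated across genes at 0.88, beside 0.497 in simulated unchanged groups against the same vehicle libraries. Shared vehicle libraries did not account for this, since with these split the correlation was still at least 0.786. Handling shared by all treated slices was tested by setting SB525334 in the place of Nint, and the correlation with Sora was lower by 0.367 and 0.46. A bound of 0.3 had been set as evidence against shared handling, but the covariance stayed at 97.3% and 85.7% of that between Sora and Nint, and the correlation fell because the SB525334 changes spread more widely. Shared handling may therefore contribute and cannot be told apart from effects common to both compounds, which is the biological explanation.

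For each comparison the libraries were also regrouped at random, with 100 splits of the same sizes counted, the real one included. The real split gave the highest count, 1 of 100, for ligation (12146, highest other 10994), Sora (4323, 3162) and Nint (3587, 483). The same held for SB525334 against vehicle (10785, 5329), Sora (10691, 8239) and Nint (10746, 8261). For these, a chance split of the libraries can be excluded at the 5% level, without adjustment over the comparisons. The labels give no animal numbers, so chance at the level of animals was not tested. For Nint against Sora 2 of 100 splits called as many, the real one with 343 genes included. That share is under 5%, but the other split called 950 genes, more than the real groups. This points to a structure among these libraries other than the 2 groups, so chance is not clearly excluded for this comparison.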

How the results depend on the processing

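Total counts, the fits without the 50 most abundant genes, without vehicle libraries 3 and 6 and without single libraries, and the axis, overlap and reversal counts under most settings were chosen after seeing the data. The tallies that follow cover all settings, those fixed in advance included, but not the fits with 1 library left out. Of genes called, 90 counts stayed within 1.5 times the reported count and 15 did not. For genes moved against ligation these were 44 and 7 counts, and for shared genes 41 and 10. All 30 axis differences kept their direction and their side of the threshold. The majority direction of calls turned with RLE factors, DESeq2 and total counts for ligation and each compound against vehicle. It also turned from the 2 groups alone for ligation, Sora and SB525334, with the authors' log CPM for ligation and SB525334, and without a low-count filter or the 50 most abundant genes for ligation, and under several settings for SB525334 against Sora or Nint. Among genes lowered by ligation, SB525334 went from 3297 increases and 1360 decreases to 1612 and 3013 with total counts. For named genes where called, 117 values kept their side of the threshold and 5 did not: log2 changes of 1.43, 1.246 and 1.12 in ENSRNOG00000006368 with Sora and -2.99 and -7.37 in ENSRNOG00000029949 with SB525334. Where not called, ENSRNOG00000048576 with SB525334 passed under 3 settings (adjusted p from 0.0158) and changed sign with the quality covariate, ENSRNOG00000029949 with Nint under 2 (from 0.0357) and with Sora under 1 (0.0091), and ENSRNOG00000006368 with Nint under 1 (0.0286).

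Requiring a log2 change of 1 left, by construction, 5695 genes for ligation, 864 for Sora, 799 for Nint, 3249 for SB525334, 40 for Nint against Sora, 3028 and 3057 for SB525334 against Sora and Nint; 1784, 1430 and 2965 genes moved against ligation by Sora, Nint and SB525334; and 608, 478 and 438 genes shared by Sora and Nint, Sora and SB525334, and Nint and SB525334. Limma-voom gave 7581 for Sora, 6452 for Nint and 3695 for Nint against Sora, with 4872 and 3434 genes moved against ligation and 4601, 3975 and 3286 shared. Fits of the 2 groups alone gave 5674 for Nint and 1605 for Nint against Sora. For the latter, plate column gave 161, the authors' log CPM 171 and DESeq2 598. The cause was not tested. Splitting the vehicle libraries, which leaves fewer libraries per contrast, gave in its 2 versions 2053 and 1815 genes moved against ligation by Sora, 1575 and 1367 by Nint and 5600 and 5575 by SB525334, and 1672 and 1579 (Sora and Nint), 1592 and 1682 (Sora and SB525334) and 1333 and 1416 (Nint and SB525334) shared genes.

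With each library left out in turn the counts ranged from 12038 to 12213 for ligation, 3976 to 4383 for Sora, 3244 to 3730 for Nint, 10599 to 10888 for SB525334, 166 to 567 for Nint against Sora, 10493 to 10894 for SB525334 against Sora and 10531 to 10885 for SB525334 against Nint. Beyond 1.5 times lay only Nint against Sora without Sora library 3 (567), 5 (191), 6 (166) or 8 (228) and without Nint library 1 (212) or 7 (195). Without vehicle libraries 3 and 6 the counts for ligation, Sora, Nint and SB525334 were 11997, 4324, 3725 and 10696.

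Replicate numbers did not pair the libraries: same-numbered libraries correlated at a mean of 0.0236 over 93 pairs, 25 of them over 0.1, and 6 of 48 libraries correlated best with their own number. With replicate number as a block the counts were 12111, 4330, 3603, 10701, 310, 10605 and 10683, in the order above, all within 1.5 times.

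The list tests and their alternatives (estimated correlation, fry, RLE factors, replicate block, quality component) were not run, since no ID had a symbol. ENSRNOG00000006368 and ENSRNOG00000048576 had no value under the filter of 5 CPM in at least 9 libraries. Both also lacked a value in several fits of the 2 groups alone. At this depth the self-test recovered 72% of genes changed by 1.5-fold for Nint and 70% for Sora, so some small changes are missed. It covered only genes at 1 CPM or more in ligated vehicle slices, so misses among scarcer genes are not known.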

Other observations

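The comparisons of gene sets below were chosen after the calls were seen, and calls alone do not show that compounds differ in a set. Of 12146 genes changed by ligation, 1271 were moved in the opposite direction by each of the 3 compounds, and 3678 by SB525334 with no call for Sora or Nint. Sora and Nint both moved 376 genes against ligation that were not called for SB525334, and 182 that SB525334 moved in the direction of ligation. Among those moved back, the fitted compound change was larger than the ligation change for 301 genes with Sora, 272 with Nint and 2061 with SB525334. No compound group was tested against sham, so these genes are not shown to lie beyond the sham level. Outside the genes called for ligation, Sora changed 549, Nint 415 and SB525334 1757.

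Of the 678 genes switched on by ligation, 444 fell with SB525334 (65.5%), 246 with Sora (36.3%) and 201 with Nint (29.6%), and fewer rose with each compound. These directions were the same with TMM, RLE and DESeq2 factors and with total counts. Of all 14775 genes tested, 5143, 1917 and 1616 fell. The set was chosen in the same vehicle libraries that the falls are measured against, and these were not split for it. With SB525334, Sora and Nint the mean was under 1 CPM again for 164, 32 and 25 of the 678 genes. Every library was under 1 CPM for 66, 2 and 2, and every library stayed at 1 CPM or more for 375, 536 and 574. SB525334 itself left 93 genes under 1 CPM in every library that were at 1 CPM or more in every vehicle library, and the opposite held for 23 (139 and 13 with total counts); unchanged values separate 9 from 10 libraries in a share of 2.17e-05 of arrangements.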
